A study of Homo sapiens with 28 samples.

How the data were processed

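H3K36me2, H3K27me3 and H3K27ac were measured by ChIPmentation in TKO cells and in TKO cells expressing wild type, D1240A or F1295A NSD2. Chromatin was fixed with 0.8% formaldehyde, sonicated, immunoprecipitated, tagmented and amplified. The 28 samples are 24 immunoprecipitates, 2 replicates for each of 4 conditions and 3 marks, and 4 inputs. The processing notes name Trimmomatic 0.36, FastQC 0.11.4, Bowtie2 2.4.5, MACS2 2.2.7.1 and the GRCh38 build. Per the file headers, each of the 12 deposited lists came from 1 run of MACS on both replicates of a condition, with paired-end fragments, a q value limit of 0.05, 1 fragment kept per position, no local background, broad region calling off and no control, so the inputs were not used in peak calling. They are not analysed here.

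The deposited pileup is, per the file headers, the number of fragments over the summit, which the authors did not scale for depth. The deposited fold enrichment is the pileup plus 1 over a single constant of each file, checked from the values, so within a list it carries the same information as the pileup. The deposited -log10 p and -log10 q values were computed by the authors against that genome-wide background. Per the file headers 61% to 87% of the sequenced fragments were duplicates, and 31097592 to 73613753 fragments per list were kept. The counts behind single peaks were given an exact Poisson interval at 95%, which covers counting error only. A gene without a peak is listed at 0, which is not a measured absence, since the lists hold only peaks past the authors' limit.

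Peaks on chromosomes 1 to 22 and X were used. Gene extents came from a RefSeq table of GRCh38 patch 14, without strand or exons, so a gene end is a window of 1 kb on either side of the start and of the end of a gene, where the plan had the gene start alone, and NSD2 exons were not placed. There, 153 protein-coding genes carry a chromosome's name with the coordinates of a separate scaffold. They were left out after results that included them had been seen, which leaves 19817 protein-coding genes. For H3K36me2 and H3K27me3, peaks less than 1 kb apart were merged, and the percent of each gene body under merged peaks was compared for the 18607 genes of at least 2 kb. A gene was called higher or lower at a difference of at least 25 percentage points. For H3K27ac a gene was gained or lost where a peak touched an end window by at least 1 bp in one list and none did in the other. The contrasts were WT against TKO, D1240A against WT and F1295A against WT. Because WT enters all of them, overlaps of their calls were not counted. With 1 list per condition no test was possible.

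The limits, the contrasts, the naming rule and 13 gene lists were fixed before the data were examined. The rule named, per contrast and mark, the 5 higher and 5 lower genes with the largest change, of at least 10 kb for H3K36me2 and H3K27me3 and by fold enrichment for H3K27ac, NSD2, and up to 4 members per list and direction. The lists hold 473 genes, as cell adhesion molecules, extracellular matrix and focal adhesion genes, t(4;14) myeloma genes, plasma cell genes, B cell genes, T cell and NK cell genes, myeloid cell genes, genes of other tissues, HOX clusters, developmental transcription factors, H3K36 and H3K27 modifying enzymes, housekeeping genes and oncogenic signalling genes. The change of each list was placed among 10000 random lists of the same size matched on gene length and mean coverage. The plan named the median change. Since most genes carry no peak and medians were near 0, the percentile of the mean was added and is the one given, as a description without a p value. Single values of some list members are not reported here.

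The alternatives fixed in the plan were no merging, merging within 3 kb, a -log10 q of at least 5, lists reduced to their highest peaks up to the same covered length, a limit of 50 points, end windows of 2.5 kb, 50 percent of the end window covered, and a stricter overlap between peaks. Alternatives chosen after seeing the data were leaving out genes in the shared blocks, meaning 1 Mb blocks in which each of the 12 lists covers at least 10% of the bases, equal covered length outside these blocks, a common minimum fold enrichment per mark, leaving out multi-copy gene families, and counting only H3K27ac peaks without an overlapping peak in the other list.

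The steps were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data, in which both lists of a comparison were copies of the WT list of a mark. For H3K36me2 and H3K27me3, 200 genes were given a change of 35 or 60 points. For H3K27ac, a short peak was added at the start of 200 genes. The recovery was 100% for H3K36me2 and at least 99.5% for H3K27me3. With peak edges shifted by 50 bp it was 99.5% for H3K27ac, where 26 of 19601 other genes were called because a shifted edge crossed a window. The planted changes exceeded the limit and the copies were otherwise nearly alike. The test therefore checks the code only, and gives no error rate for the deposited lists, which differ far more.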

Results

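ChIPmentation, a chromatin immunoprecipitation in which sequencing adapters are inserted by a transposase on the precipitated chromatin, was used to map H3K36me2, H3K27me3 and H3K27ac in TKO cells. TKO is a derivative of the KMS-11 myeloma line, labelled as WHSC1(+/-), where WHSC1 is an older name of NSD2. NSD2 is the histone methyltransferase that places H3K36me2. The TKO cells were compared with TKO cells expressing wild type NSD2 (WT), the D1240A form or the F1295A form, to ask how mutant NSD2 may change chromatin marks. Each condition and mark had 2 replicates, and 4 input samples completed the 28 samples. The deposited values are 12 peak lists, 1 per condition and mark, each called on both replicates together, so there are no replicates per list, no replicate error and no significance test. The lists rest on 62550152 to 69211726 fragments for H3K36me2, 31097592 to 44812488 for H3K27me3 and 67939521 to 73613753 for H3K27ac after duplicates were removed. All coordinates are GRCh38.

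H3K36me2, the product of NSD2, covered less of the genome in the WT list than in the TKO list. Its peaks spanned 94.3 Mb in TKO, 73.0 Mb in WT, 77.1 Mb in D1240A and 94.3 Mb in F1295A. The number of peaks was 119446 in TKO, 72582 in WT, 99096 in D1240A and 116725 in F1295A. H3K27me3, the mark placed by the Polycomb enzymes EZH2 and EZH1, spanned 73.7 Mb in TKO, 70.2 Mb in WT, 63.6 Mb in D1240A and 64.0 Mb in F1295A. H3K27ac, which marks active promoters and enhancers, spanned 115 Mb in TKO, 107 Mb in WT, 112 Mb in D1240A and 117 Mb in F1295A. In 94 blocks of 1 Mb, together 3.08% of the genome, each of the 12 lists covered at least 10% of the bases. These shared blocks, most of them next to centromeres but with gene-rich runs of 15 Mb and 2 Mb on chromosome arm 1q and of 1 Mb (31 genes) and 2 Mb (75 genes) on 12q, held 65.2% of the WT H3K36me2 length and 47.4% of that in TKO. Outside them H3K36me2 spanned 49.6 Mb in TKO, 25.4 Mb in WT, 33.8 Mb in D1240A and 49.2 Mb in F1295A, which put TKO at 1.95 times WT.

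**Figure D1:**
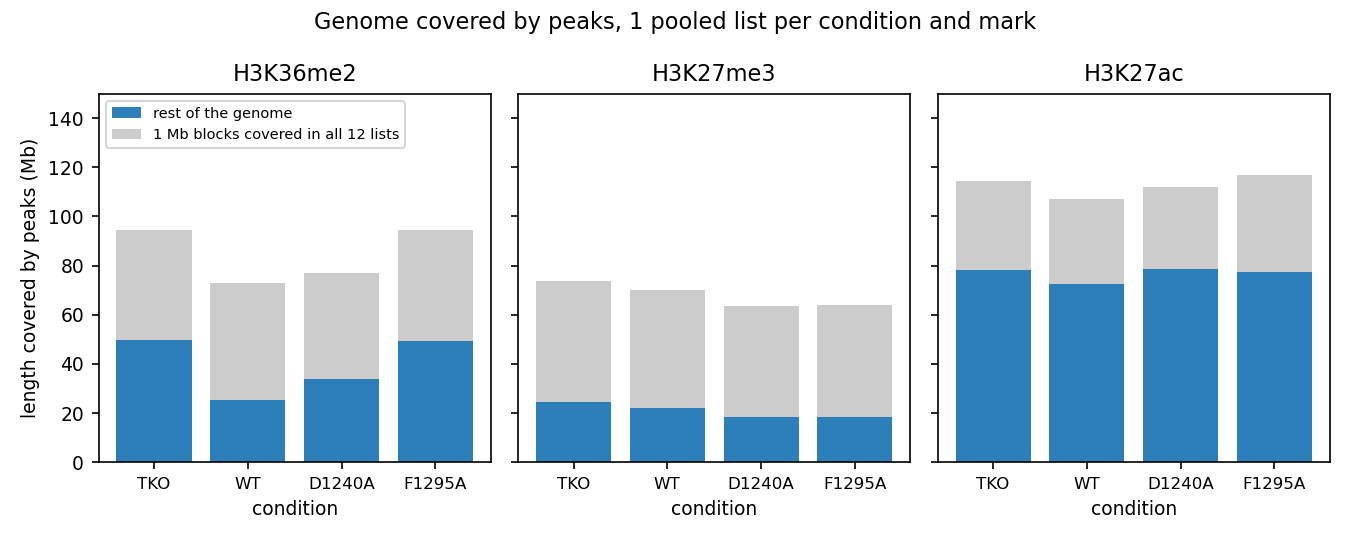
Length of the genome covered by peaks in Mb (vertical axis) in each condition (horizontal axis) for H3K36me2, H3K27me3 and H3K27ac, with 1 pooled list per bar and no error. Blue parts lie in the rest of the genome and grey parts in the 1 Mb blocks covered in all 12 lists. The blue H3K36me2 part is 49.6 Mb in TKO and 25.4 Mb in WT.

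With wild type NSD2 added to TKO cells, H3K36me2 peaks covered less of CREG1, C17orf99, ITGB7, COPZ1 and PRIM1. Peak coverage does not give the total amount of a mark, since each list was called against its own genome-wide background. CREG1, a secreted glycoprotein gene on chromosome 1 (167541013 to 167553762), had 93.7% of its body under H3K36me2 peaks in TKO and 2.1% in WT. C17orf99 was covered over 80.6% in TKO and 4.4% in WT, COPZ1, which encodes a coatomer subunit, over 92.3% and 24.6%, and PRIM1, which encodes the DNA primase catalytic subunit, over 86.7% and 19.9%. Coverage was higher in WT over FCGR2B, the inhibitory Fc gamma receptor gene, with 21.8% in TKO and 60.5% in WT. ATP1A4, HRNR, OR6C74 and GOLGA6L22 were also higher in WT. ITGB7, PRIM1, FCGR2B, ATP1A4 and HRNR lie in shared blocks. OR6C74 and GOLGA6L22 belong to multi-copy gene families, as judged by their symbols. Of 18607 protein-coding genes of at least 2 kb, 460 had at least 25 percentage points less of their body covered in WT than in TKO, and 31 had at least 25 points more. With each list reduced to the same covered length the counts were 180 lower and 75 higher, and without genes in the shared blocks they were 325 lower and 16 higher.

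Among cell adhesion molecules, the group in the title of the series, ITGB7 and CDH17 were the 2 of 76 measured genes with lower H3K36me2 in WT, and none was higher. ITGB7, an integrin beta chain by which lymphocytes and myeloma cells adhere, lies on chromosome 12 (53191323 to 53207251) in a shared block. Its body was covered over 91.1% in TKO, 23.1% in WT, 85.1% in D1240A and 79.8% in F1295A. CDH17, a cadherin gene on chromosome 8 (94127162 to 94217278), was covered over 43.4% in TKO, 9.1% in WT, 28.5% in D1240A and 44.3% in F1295A. The mean change of the adhesion list was -2.78 points, at percentile 19.3 of 10000 random lists matched on gene length and coverage. With equal covered length 1 adhesion gene was lower and 1 was higher.

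Of 27 plasma cell genes, MCL1, JCHAIN and ELL2 had lower H3K36me2 in WT. MCL1, an anti-apoptotic gene on which plasma cells depend, was covered over 85.6% in TKO and 14.9% in WT, JCHAIN, the joining chain of polymeric immunoglobulins, over 58.7% and 2.9%, and ELL2, an elongation factor that favours secretory immunoglobulin transcripts, over 49.8% and 8.3%. In each of 4 more lists 1 gene was lower, namely FCRLA among B cell genes (76.4% in TKO, 0.0% in WT), EED, a core subunit of Polycomb repressive complex 2, among the H3K36 and H3K27 enzymes (57.3%, 14.5%), NFKB2 among oncogenic signalling genes (36.2%, 0.0%) and PSMB4 among housekeeping genes (76.3%, 40.1%). S100A9, a calprotectin gene of the myeloid list, was higher in WT (0.0% in TKO, 39.2% in WT), and the mean change of that list, 3.63 points, lay at percentile 99.95 with a median of 0.00. EED and NFKB2 no longer passed at equal covered length, where 2 plasma cell genes were lower and 1 higher. MCL1, FCRLA, PSMB4 and S100A9 lie in shared blocks. Outside these blocks none of the 14 measured myeloid genes passed the limit, while the percentile of the myeloid list includes the genes inside them. No member passed the limit in the lists of extracellular matrix and focal adhesion genes, t(4;14) myeloma genes, T cell and NK cell genes, genes of other tissues, HOX clusters or developmental transcription factors.

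H3K27me3 was higher in WT than in TKO over the HOXC cluster, a set of developmental regulators silenced by Polycomb in most adult cells. Of 38 measured HOX genes 7 were higher in WT and none was lower. HOXC12 was covered over 15.5% in TKO and 100% in WT, HOXC6 over 33.7% and 79.4%, HOXC5 over 30.4% and 69.9%, and HOXC8 over 63.0% and 100%. The peaks over HOXC12 were weak in both lists, with 15 and 19 fragments in TKO and 17 to 22 in WT. The list minimums were 11 in TKO and 12 in WT. The 100% of HOXC12 includes gaps of less than 1 kb between its WT peaks, so the difference is not a complete switch. HOXC9, HOXC4 and HOXB9 also passed, and HOXC4, HOXC5 and HOXC6 overlap each other in the annotation. Over the cluster as a whole (chromosome 12, 53930831 to 54064030) H3K27me3 peaks covered 44.5% in TKO, 71.3% in WT, 41.3% in D1240A and 50.5% in F1295A. The mean change of the HOX list lay at percentile 100 of the 10000 random lists, but its median change was 0.00, and 6 of the 7 genes are neighbours in HOXC and not independent. With equal covered length 5 HOX genes were higher and none lower. FOS, an immediate early transcription factor gene, was covered over 7.0% in TKO and 47.0% in WT, but did not pass at equal covered length.

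Beyond these lists, H3K27me3 was higher in WT over TBC1D3L (42.7% in TKO, 96.1% in WT), TBC1D3B (9.0%, 61.1%) and CHIT1, the chitotriosidase gene of macrophages (2.3%, 39.6%). It was lower over IKZF4, a lymphoid transcription factor of the Ikaros family (64.5%, 25.8%), CD160, a receptor of NK and T cells (76.5%, 43.1%), CTSK, the cathepsin K gene (76.9%, 46.2%), POLR3GL and GOLGA6L22. IKZF4, CD160, CTSK and POLR3GL lie in shared blocks, and TBC1D3L, TBC1D3B and GOLGA6L22 belong to multi-copy families. In all, 53 genes were higher and 37 lower. These counts fell to 37 higher and 11 lower without genes in the shared blocks. No gene of the other 11 lists passed the limit for H3K27me3, and of these the modifying enzymes lay lowest, at percentile 2.28 for a mean change of -0.43 points.

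**Figure D2:**
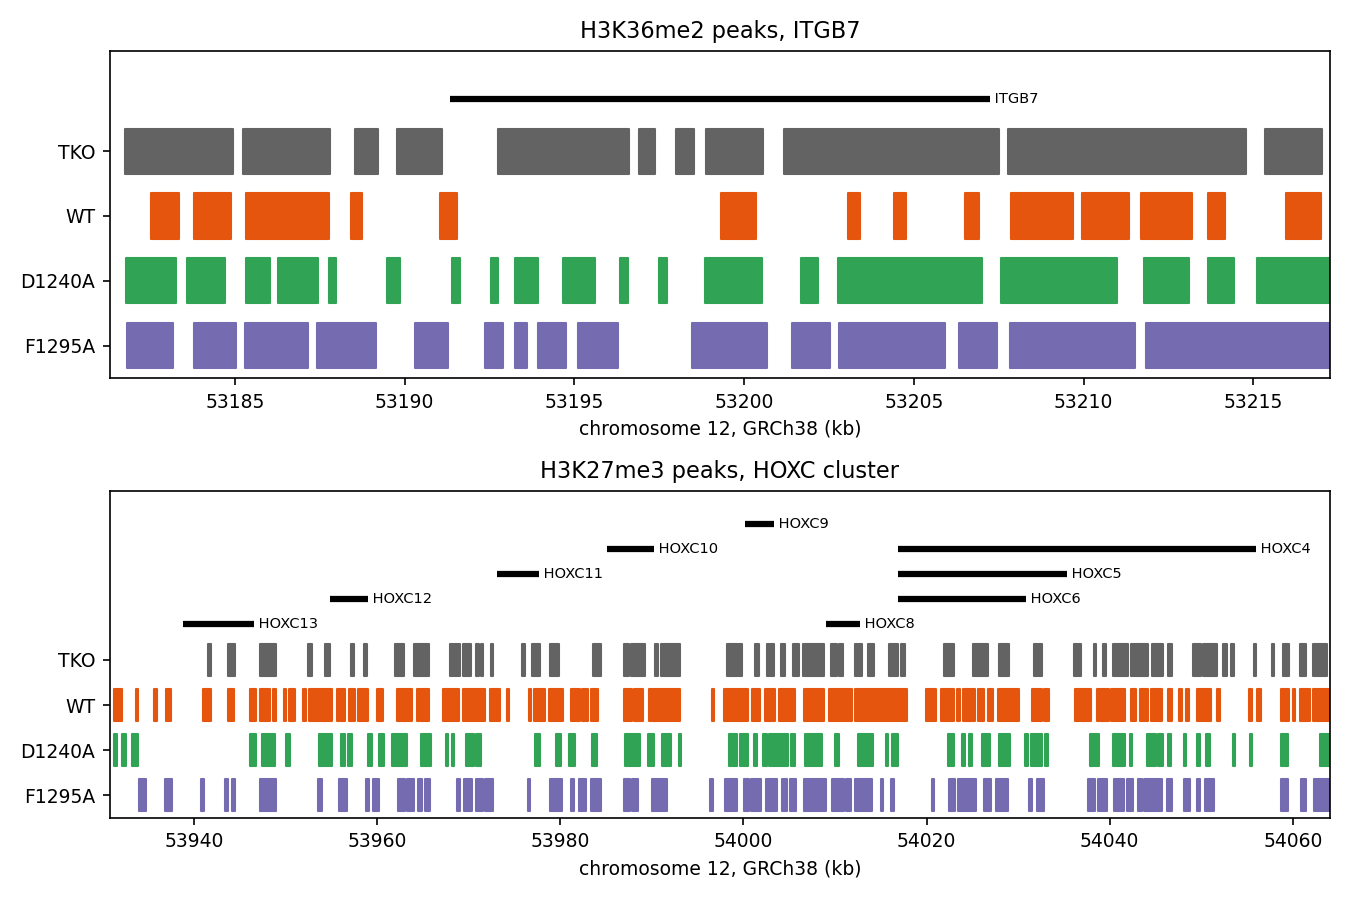
Peaks of each condition drawn to scale along chromosome 12 in kb (GRCh38), with H3K36me2 peaks around ITGB7 in the upper map and H3K27me3 peaks over the HOXC cluster in the lower map; black bars are annotated genes. H3K36me2 covers 93.5% of the upper region in TKO and 50.3% in WT, and H3K27me3 covers 44.5% of the lower region in TKO and 71.3% in WT, with peaks less than 1 kb apart merged.

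H3K27ac at gene ends was present in WT and absent in TKO at 303 genes, and absent in WT and present in TKO at 361. STXBP5L, a syntaxin-binding gene expressed in neurons, had the strongest WT peak at a gene end with no overlapping TKO peak (chromosome 3, 120908258 to 120910125), at a fold enrichment of 13.3 and a pileup of 87 fragments (exact Poisson 95% interval 69.7 to 107). In 29 of the 30 entries that the naming rule gave for H3K27ac over all contrasts, including BANP, IFFO1 and TNFRSF14, the peak reached a gene's 1 kb window in one list and overlapped a peak of the other list that ended outside it. Without such cases 282 genes were gained and 306 lost. The genes named in the rest of this paragraph were chosen after their values were seen, as the strongest without an overlapping peak. CCL3L3, a chemokine gene (9.07), ARHGAP28 (7.41), ADAMTS3 (6.95) and CACNA2D1 (6.80) had a fold enrichment in WT and no peak in TKO. CBLB, a ubiquitin ligase gene that restrains lymphocyte activation (7.20), MRPS6 (6.30) and TRIM62 (5.70) had a peak in TKO and none in WT.

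At the ends of adhesion genes, H3K27ac peaks of JAM2, CNTNAP2, EPCAM and CNTN1 were listed in WT and not in TKO, and those of ITGA5, ITGA3, ITGA8 and ITGB2 in TKO and not in WT. Their fold enrichments were low, from 3.02 for CNTN1 to 5.29 for JAM2 in WT, and from 3.15 for ITGA8 to 5.40 for ITGB2 in TKO, whose peak overlapped a WT peak outside the window. FOS had a peak in WT (4.99) and none in TKO, as did MET (2.87), a receptor tyrosine kinase gene of the oncogenic list. Peaks in TKO and not in WT were those of CD7 and GATA3 among T cell and NK cell genes, CD83 among B cell genes, SRC and COL6A1 among extracellular matrix and focal adhesion genes, and GRIN1 among genes of other tissues. PXN was gained in the matrix list. Of the HOX genes HOXA5 was gained, and HOXA3 and HOXC11 were lost, but the TKO peaks of GRIN1 and HOXA3 overlapped WT peaks outside the window. Among developmental transcription factors 2 were gained, FOXA1 among them, and 4 were lost, DLX2, EN2 and TBX2 among them. The plasma cell, t(4;14), myeloid, modifying enzyme and housekeeping lists had no change. The balance of gained and lost genes turned with the setting, with 467 gained and 215 lost at equal covered length, where the matrix list had 2 gained and none lost and 1 T cell and NK cell gene was lost.

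The D1240A form was compared with WT to ask what the exchange at that position changes. H3K36me2 was higher in D1240A over ITGB7 (23.1% in WT, 85.1% in D1240A), OR2T2 (15.5%, 87.8%), PIP4K2C, a phosphoinositide kinase gene (26.8%, 83.2%), C17orf99 (4.4%, 60.6%) and MYL12BP2 (39.2%, 93.4%). It was lower over OR2A42 (40.8%, 4.0%), the B cell receptor-like gene FCRL1 (67.3%, 30.5%), HRNR, CD84 and CFAP45. OR2T2 and OR2A42 belong to multi-copy families. In TKO, ITGB7 (91.1%), PIP4K2C (92.9%), C17orf99 (80.6%) and MYL12BP2 (100%) were covered over more than in D1240A, and OR2T2 (56.6%) over less. The contrast alone does not tell a gain in D1240A from a low WT list. In all, 163 genes were higher and 27 lower. ITGB7 was the only adhesion gene past the limit, and the list's mean change of 1.76 points lay at percentile 97.9 of the random lists while its median change was 0.00. MCL1 (14.9%, 47.2%) and TNFRSF17, the plasma cell receptor BCMA (0.0%, 32.6%), were higher among plasma cell genes, FCRLA (0.0%, 42.4%) among B cell genes and PSMB4 (40.1%, 100%) among housekeeping genes. The remaining 9 lists had no gene past the limit, though the mean change of the myeloid list, -2.10 points, lay at percentile 0.9, also with a median of 0.00. Without the shared blocks 77 genes were higher and 17 lower, and ITGB7, MCL1, FCRLA and PSMB4 lie in these blocks. At equal covered length outside the blocks the counts were 34 higher and 24 lower.

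H3K27me3 was lower in D1240A than in WT over 119 genes and higher over 7. Of the HOX genes 7 were lower and none higher, with a mean change of -9.54 points, at percentile 0 of the random lists, but a median change of 0.00, and all but HOXB9 lie in HOXC. HOXC8 was covered over 100% in WT and 17.9% in D1240A, HOXC12 over 100% and 32.0%, HOXC6 over 79.4% and 33.5%, and HOXC11 over 53.2% and 10.0%. MEX3A (100%, 22.8%), HCN3, a pacemaker channel gene (100%, 49.2%), SEMA6C (85.2%, 35.4%), TBC1D3L (96.1%, 47.1%) and LYSMD1 (60.6%, 11.6%) had the largest losses among genes of at least 10 kb. TBC1D3L belongs to a multi-copy family. BNIPL was higher (35.4%, 75.2%). FOS (47.0%, 0.0%), FCGR3A among myeloid genes (56.0%, 26.7%) and TNNT2, cardiac troponin T, among genes of other tissues (37.6%, 11.1%) were lower but did not pass at equal covered length, and no gene of the other 9 lists passed. Without the shared blocks, which hold HOXC11, HOXC12, MEX3A, HCN3, SEMA6C, LYSMD1, BNIPL and FCGR3A, 57 genes were lower and 2 higher. The D1240A list rests on 33219802 fragments and the WT list on 44812488, and at equal covered length 47 genes were lower and 16 higher, among them 4 HOX genes lower.

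H3K27ac was gained at 431 gene ends in D1240A against WT and lost at 203. The strongest gain by the naming rule was TNFRSF14, a receptor of the TNF family (47.4 in D1240A, no WT peak within the end windows). The strongest loss was BANP (34.5 in WT). Both had overlapping peaks in the other list. Without overlapping peaks the counts were 361 and 187, and CBLB (7.23) and HLA-DOA, an MHC class II chaperone gene (6.26), chosen after their values were seen, had the strongest gains, while BARX2 (5.59 in WT) had the strongest loss. ITGB2, whose peak overlapped a WT peak, ITGA3 and ITGA8 were gained among adhesion genes, while at equal covered length 3 adhesion genes were gained and 3 lost. CD7, GATA3 and GNLY were gained among T cell and NK cell genes, at percentile 99.3 of the random lists, with fold enrichments of 3.05 to 3.69. HOXA3, HOXC11, HOXB9, HOXC8 and HOXC13 were gained. Among developmental transcription factors 4 were gained, EN2, DLX1 and DLX2 among them. No HOX gene and no developmental transcription factor was lost, but with equal covered length 3 HOX genes were gained and 1 lost. CD83 and CD79A were gained and CR2 lost among B cell genes, PTK2 and VTN gained and PXN lost among matrix and focal adhesion genes, MET lost and GRIN1 gained, and no matrix gene was gained at equal covered length. The peaks of HOXA3 and GRIN1 overlapped WT peaks outside the window. The plasma cell, t(4;14), myeloid, modifying enzyme and housekeeping lists had no change. At equal covered length 316 were gained and 300 lost, and outside the shared blocks the balance turned at that setting, with 229 gained and 346 lost.

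The F1295A form was compared with WT for the other exchanged position. H3K36me2 was higher in F1295A over THBS3, a thrombospondin gene (11.7% in WT, 78.6% in F1295A), PIP4K2C (26.8%, 92.3%), COPZ1 (24.6%, 90.0%), C17orf99 (4.4%, 69.4%) and DCST2 (28.4%, 92.2%). In TKO, PIP4K2C (92.9%), COPZ1 (92.3%) and C17orf99 (80.6%) were covered over more than in F1295A, and THBS3 (54.5%) and DCST2 (70.0%) over less. The contrast alone does not tell a gain in F1295A from a low WT list. H3K36me2 was higher in F1295A over 407 genes and lower over 9. GOLGA6L22, of a multi-copy family, was the only lower gene of at least 10 kb. Of the adhesion genes ITGB7 (23.1%, 79.8%), ITGA5, the fibronectin receptor alpha chain (2.1%, 46.5%), and CDH17 (9.1%, 44.3%) were higher and none was lower, at percentile 98.2 for the mean change of 3.28 points with a median change of 0.00. MCL1 (14.9%, 87.2%) and ELL2 (8.3%, 34.9%) were higher among plasma cell genes, S100A9 (39.2%, 91.9%) and S100A8 (37.3%, 66.5%) among myeloid genes, FCRLA (0.0%, 60.4%) among B cell genes, HOXC11 (0.0%, 26.8%) among HOX genes, PSMB4 (40.1%, 100%) among housekeeping genes and IL6R, the interleukin 6 receptor gene (70.2%, 95.3%), among oncogenic signalling genes. The other 6 lists had none. Without the shared blocks, which hold THBS3, PIP4K2C, DCST2, ITGB7, MCL1, FCRLA, PSMB4, HOXC11, IL6R and both S100A genes, 218 genes were higher and 8 lower. At equal covered length 197 genes were higher and 24 lower, outside the blocks 50 and 23, with 1 adhesion gene, 1 plasma cell gene and no myeloid, HOX or oncogenic signalling gene past the limit in the former.

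H3K27me3 was lower in F1295A than in WT over 93 genes and higher over 10. HOXC12 (100%, 25.2%), HOXC11 (53.2%, 6.3%), HOXC6 (79.4%, 48.6%) and HOXC10 (65.3%, 35.1%) were lower and no HOX gene was higher, at percentile 0.16 of the random lists with a median change of 0.00, again neighbours in HOXC. HOXC8 was covered over 100% in both lists. MRPS21 (100%, 47.4%), MEX3A (100%, 50.4%), SEMA4A, a semaphorin gene (99.5%, 51.2%), PLEKHO1 (73.4%, 29.0%) and EPS8L3 (57.3%, 17.1%) were lower among genes of at least 10 kb. GOLGA6L22, of a multi-copy family, was higher (24.0%, 53.3%). FOS (47.0%, 0.0%), whose list lay at percentile 1.08 but which did not pass at equal covered length, and S100A8 were lower, and the other 10 lists had no gene past the limit. Without the shared blocks, which hold HOXC10, HOXC11, HOXC12, MRPS21, MEX3A, SEMA4A, PLEKHO1 and S100A8, 40 genes were lower and 6 higher. The F1295A list rests on 31097592 fragments, and at equal covered length 34 genes were lower and 21 higher, among them 2 HOX genes lower, and outside the blocks 15 were lower and 10 higher.

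H3K27ac was gained at 358 gene ends in F1295A against WT and lost at 222. By the naming rule CYP7B1, an oxysterol hydroxylase gene (44.4), had the strongest gain and NFU1, an iron-sulfur cluster gene (34.9 in WT), the strongest loss, both with overlapping peaks in the other list. Without overlapping peaks 296 were gained and 207 lost. Chosen after their values were seen, ETV4, an ETS factor gene, had the strongest gain (5.56), and MAOA, the monoamine oxidase A gene (8.01 in WT), and NR6A1 (6.65 in WT) had the strongest losses. COL1A1 and PXN were among the matrix and focal adhesion genes lost and none was gained, at percentile 2.71 of the random lists. Among adhesion genes ITGB2, ITGA3 and ITGAX were gained and CNTN1 was lost, with 2 gained and 2 lost at equal covered length. CD7 and GATA3 were gained among T cell and NK cell genes, and CD79A and CD83 gained and CR2 lost among B cell genes. Among developmental transcription factors 2 were gained, FOXL2 among them, and 1 was lost. HOXC11 and GRIN1 were gained, and MET was lost. The peaks of ITGB2, CD79A and GRIN1 overlapped WT peaks, and no T cell and NK cell gene and no HOX gene was gained at equal covered length. The plasma cell, t(4;14), myeloid, modifying enzyme and housekeeping lists had no change. At equal covered length the balance turned, with 189 gained and 408 lost.

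**Figure D3:**
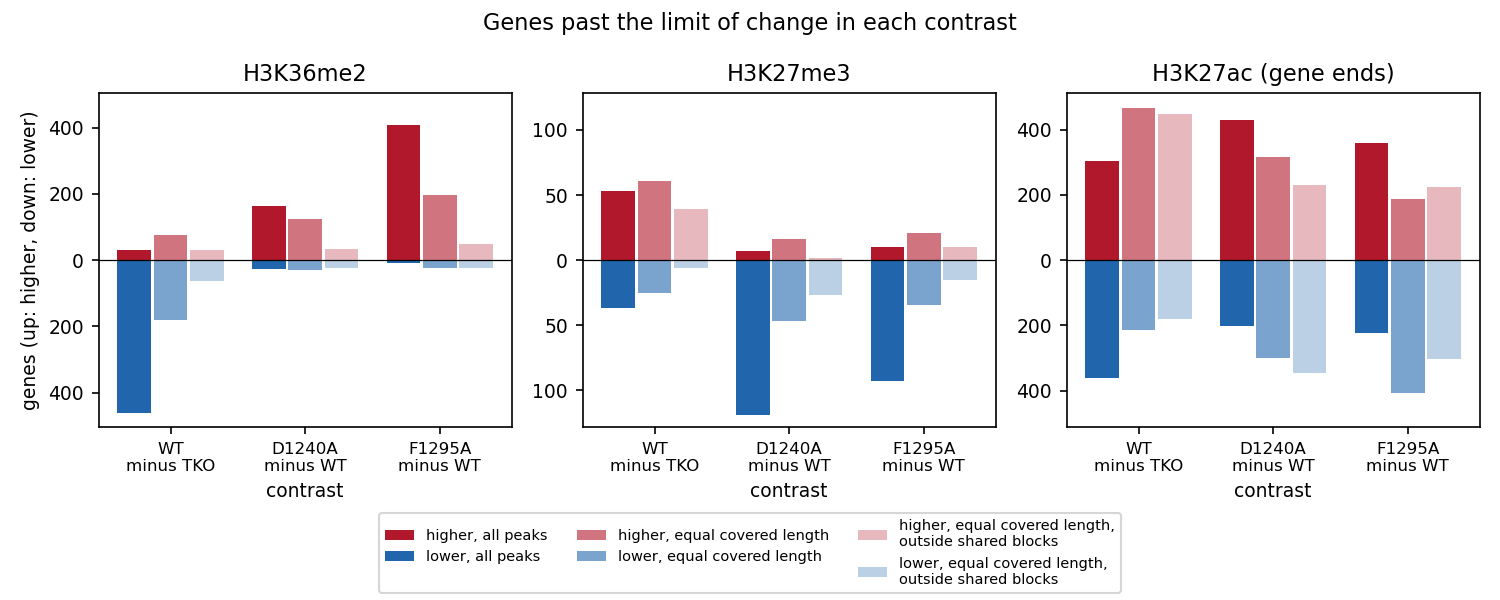
Number of genes (vertical axis, higher upward and lower downward) past the limit of change in each contrast (horizontal axis) for each mark, counted with all peaks, with lists of equal covered length, and with equal covered length outside the shared blocks. With all peaks H3K36me2 is higher at 31 and lower at 460 genes in WT against TKO, and higher at 407 and lower at 9 in F1295A against WT. The H3K27ac balance turns between settings.

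In the 1341 windows of 10 kb whose H3K36me2 coverage was at least 50 percentage points lower in WT than in TKO, mean H3K36me2 coverage was 72.8% in TKO and 8.96% in WT. H3K27ac covered 52.3% of them in TKO and 46.9% in WT, and H3K27me3 1.91% and 1.23%. In the 1270 of these windows outside the shared blocks, H3K27ac covered 52.0% in TKO. Of the whole TKO H3K36me2 length 52.1% lay in H3K27ac peaks, and 33.1% outside the shared blocks. The latter are shares of peak length and the former are shares of all bases of a window, so they cannot be compared directly. The 102 windows gained in WT had H3K27me3 over 61.0% in TKO and 58.1% in WT, and 51 of them lay outside the shared blocks. Outside these blocks 48.4% of the TKO H3K36me2 length lay in gene bodies, against 33.8% in WT, 42.7% in D1240A and 45.3% in F1295A. Gene bodies take up 40.2% of the genome, blocks included, so the WT share alone lay below that of the genome. H3K27me3 peaks lay inside H3K36me2 peaks over 39.0% of their length in TKO, 48.1% in WT, 45.7% in D1240A and 44.5% in F1295A, outside the blocks. These shares were 23.11 (TKO) to 55.53 (WT) times those expected from genome coverage. There, H3K27me3 peaks also lay inside H3K27ac peaks over 18.19% (WT) to 26.64% (F1295A) of their length. That was 6.953 (TKO) to 10.12 (F1295A) times expectation. The lists were called without a control, and the cause of this sharing was not tested. Whether a change at a gene is particular to a single mark was not tested either. The Jaccard index between the lists of a mark, outside the blocks, was 0.21 to 0.29 for H3K36me2, 0.37 to 0.41 for H3K27me3 and 0.71 to 0.74 for H3K27ac.

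NSD2 itself (chromosome 4, 1871393 to 1982192, gene 7468) carried no H3K36me2 or H3K27me3 peak in any list. All 4 H3K27ac lists had a peak just inside its annotated start, with a fold enrichment of 12.8 in TKO, 11.04 in WT, 13.2 in D1240A and 13.8 in F1295A. Each also had a peak just before the start, at 12.6 in TKO, 14.06 in WT, 16.22 in D1240A and 15.42 in F1295A. Inside the gene, a peak at 1900637 to 1901276 was present in WT, D1240A and F1295A and absent in TKO. Its pileup was 179 fragments in WT (exact Poisson 95% interval 154 to 207), 200 in D1240A (173 to 230) and 107 in F1295A (87.7 to 129), with fold enrichments of 27.2, 32.3 and 17.2. A weaker peak at 1918140 to 1918591 had 36, 59 and 29 fragments in the same lists and was absent in TKO. The intervals cover counting error only.

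**Figure D4:**
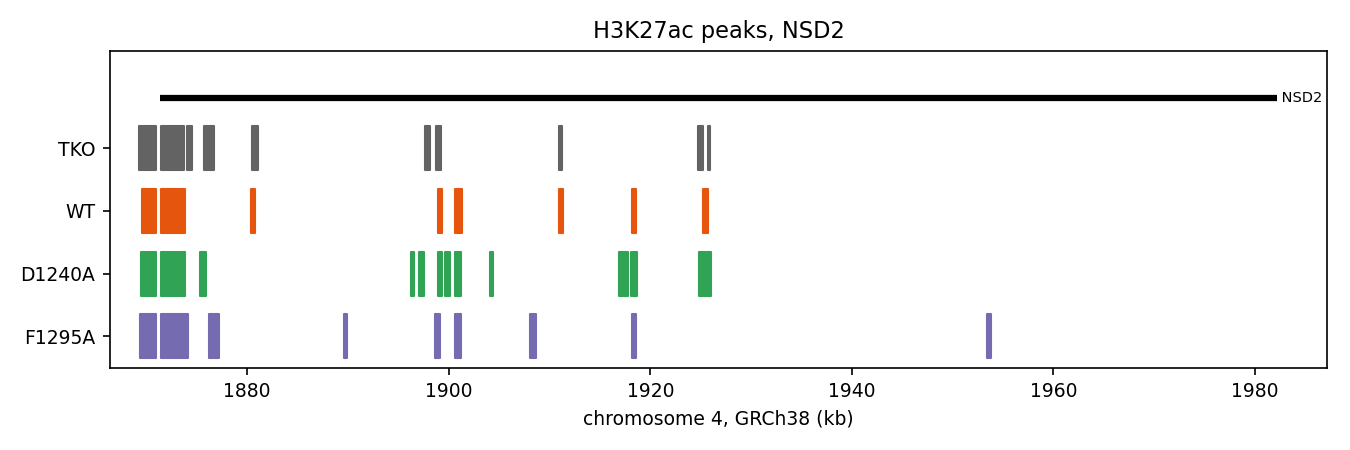
H3K27ac peaks in each condition drawn to scale along chromosome 4 in kb (GRCh38) around NSD2, whose annotated extent is the black bar. The peak at 1900637 to 1901276 is present in WT, D1240A and F1295A and absent in TKO.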

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

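The tests of depth and of the shared blocks for H3K36me2 and all tests on NSD2 were chosen after the results they address had been seen, the test of 1q outside the blocks replaced one inside them whose value had been seen, and the gene set of the H3K36me2 test at equal covered length was corrected after its value had been seen.

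H3K36me2 peaks covered less of the genome in WT than in TKO. A difference in depth as the whole cause is argued against. TKO peaks that reach the minimum WT pileup after scaling to the WT number of fragments were 1.54 times the WT peaks (1.526 to 1.555). That binomial interval takes each peak as independent and covers no variation between replicates. The test covers the number of fragments kept only. Duplicates made up 77% of the H3K36me2 fragments in WT, 73% in D1240A, 72% in TKO and 65% in F1295A, and a part played by this difference was not tested. The shared blocks do not account for the difference in covered length, since outside them TKO covered 1.951 times the length of WT. A lower enrichment of the whole WT library, with the order of regions kept, and a change at particular genes cannot be told apart. With lists of equal length outside the blocks, 30 of 93 changed genes were higher in WT, or 32.26%. The exact 95% interval, 22.93 to 42.75, reaches past 40%, the lower bound set for an unchanged order. It takes genes as independent, though neighbouring genes can share peaks, and covers no variation between replicates. Peak coverage gives no total amount of H3K36me2, so a change in that amount was not measured. An effect of wild type NSD2 itself stays open and was not tested, since there is 1 list per condition.

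Stretches of 1 Mb were covered by peaks of all 3 marks in all 4 conditions. Repeats folded together in the reference and called without a control could not be tested by the sharing of bases between H3K27me3 and H3K27ac in gene-poor stretches, where the ratio over expectation was 1.359 at the lowest and could be no higher than 1.387 to 1.413, so repeats and true marks cannot be told apart there. H3K27ac at gene ends on chromosome arm 1q outside the stretches was compared with that on other arms. The median fold enrichment on 1q was at least 1.294 times that on other arms in each of the 4 lists. The bootstrap 95% interval was 1.184 to 1.49 in F1295A, which had the lowest ratio. In WT it reached down to 1.124, and the bootstrap takes genes as independent. Extra copies of 1q, a common lesion of myeloma, would give such a ratio. Chromosome 18 reached 1.294 to 1.366 over the others, so such a ratio is not particular to 1q, and higher activity of genes on 1q would give it too. The gene-rich stretches on 12q are not covered by this test, chromosome 12 outside them lay at 0.8142 to 0.8421 of the others, and no cause of those stretches and no biological explanation was tested.

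Of the H3K27ac peaks inside NSD2, a stronger and a weaker one were present in WT, D1240A and F1295A and had no counterpart in TKO. Extra copies of NSD2 sequence that raise every library alike are argued against by the 0 peaks of H3K36me2 and H3K27me3 inside the gene in these lists, and for the stronger site, a place among many new H3K27ac sites is argued against by 0 other peaks as strong in the 3 lists and absent in TKO. The edges of the stronger site lay within 17 bp between the lists, as close as in 2.635% of 683 matched peaks with a median of 372 bp, which is consistent with acetylated chromatin of an added NSD2 coding sequence whose reads stop at an exon edge. The weaker site may instead be one of many, since 37 other peaks were as strong and absent in TKO. Exon positions were not used, so neither site was placed on an exon.

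The covered length of H3K27ac was higher in F1295A than in TKO by 2.3 Mb and lower in D1240A than in TKO (a difference of -2.5 Mb), a contrast in direction between the forms that was not tested. Outside the shared blocks both directions turned, with 78.39 Mb in TKO, 78.55 Mb in D1240A and 77.33 Mb in F1295A. HOXC8 was covered by H3K27me3 over 37.0 percentage points more in F1295A than in TKO and less in D1240A (a difference of -45.1 points), which was not tested either.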

How the results depend on the processing

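Leaving out genes in the shared blocks, equal covered length outside them, the common minimum fold enrichment, leaving out multi-copy families and requiring H3K27ac peaks without an overlapping peak were chosen after the data were seen. No paired analysis was possible because each list pools both replicates of a condition, and for the same reason no replicate could be left out. In every setting H3K36me2 was lower at more genes than it was higher in WT against TKO, and the reverse held for D1240A and F1295A against WT. The margin was narrow in D1240A against WT at equal covered length outside the blocks, with 34 higher and 24 lower. H3K27me3 was higher at more genes in WT against TKO and lower at more in both forms against WT in every setting. All settings reuse the same lists and WT enters each contrast, so their agreement is not independent evidence. The balance of H3K27ac turned in WT against TKO at equal covered length, there also outside the shared blocks, and with windows of 2.5 kb (376 gained, 369 lost), in F1295A against WT at equal covered length within and without the blocks, and in D1240A against WT at equal covered length outside the blocks only. The cause was not tested. With the common minimum fold enrichment, and with only H3K27ac peaks without an overlapping peak, every count stayed within 1.5 times. The H3K27me3 lists differ in depth, with 31097592 fragments in F1295A and 44812488 in WT.

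Below, counts are higher then lower genes, and those not given stayed within 1.5 times. Without merging, H3K36me2 had 10 and 294 genes in WT against TKO, 67 and 5 in D1240A against WT, and 3 lower in F1295A against WT, and H3K27me3 had 23 and 13, 0 and 55, and 2 and 37. With peaks within 3 kb merged, H3K36me2 had 76 and 958, 373 and 68, and 799 and 33, and H3K27me3 107 and 102, 37 and 207, and 33 and 220. Merging less or more covers less or more of each gene, so these counts move by construction. With a -log10 q of at least 5, H3K36me2 had 248 lower in WT against TKO and 16 lower in D1240A against WT, and H3K27me3 16 lower in WT against TKO and 56 lower in F1295A against WT. The cause was not tested.

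At equal covered length, H3K36me2 had 75 and 180 genes in WT against TKO and 197 and 24 in F1295A against WT, and H3K27me3 had 16 and 47 in D1240A against WT and 21 and 34 in F1295A against WT. H3K27ac had 467 and 215 in WT against TKO and 189 and 408 in F1295A against WT. The stricter limit of 50 points left fewer genes by construction, with 0 and 77, 20 and 2, and 79 and 0 for H3K36me2 and 13 and 4, 0 and 17, and 1 and 10 for H3K27me3. Requiring 50 percent of the end window left 11 and 13, 22 and 0, and 14 and 1 for H3K27ac.

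Without the shared blocks fewer genes were counted, with 16 higher in WT against TKO, 77 and 17 in D1240A against WT and 218 higher in F1295A against WT for H3K36me2, and 11 lower, 2 and 57, and 6 and 40 for H3K27me3. Without multi-copy families 15 genes were higher for H3K36me2 in WT against TKO, 14 lower in D1240A against WT and 2 lower in F1295A against WT. At equal covered length outside the blocks, H3K36me2 had 30 and 63 in WT against TKO, 34 and 24 in D1240A against WT, and 50 and 23 in F1295A against WT. H3K27me3 had 39 and 6, 2 and 27, and 10 and 15, and H3K27ac had 448 and 180, 229 and 346, and 224 and 304. The cause was not tested. Of the peaks of the TKO H3K36me2 list 40.02% overlapped a WT peak by at least 1 bp, 33.3% over at least 50 percent of the peak and 59.7% at a -log10 q of at least 5. Of 27 overlap percentages, 15 of them with the WT or TKO list of a mark and the others between marks, 26 were higher and 1 lower at that limit, and all 27 were lower without the shared blocks. Overlaps of F1295A with D1240A are not among them, and the share of F1295A H3K27ac peaks that overlap a D1240A peak rose from 75.76% to 76.13% without the blocks. The 15 were all lower when 50 percent of the peak had to be covered. Of 27 counts of list members for H3K36me2 and H3K27me3 that were not 0, 16 were lower at equal covered length, 1 was higher and 10 stayed within 1.5 times, the lower ones including the plasma cell list for H3K36me2 and the HOX list for H3K27me3 in both forms against WT.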

Other observations

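The genes named here were chosen after their values were seen, as those of at least 10 kb with the largest change outside the shared blocks. SARNP, an mRNA export gene on chromosome 12 (55752463 to 55817724), had H3K36me2 over 85.7% of its body in TKO, 25.6% in WT, 53.7% in D1240A and 82.9% in F1295A. RASA4B, a Ras GTPase-activating gene, was covered over 62.0% in TKO, 10.5% in WT, 53.2% in D1240A and 43.7% in F1295A. RO60, which encodes an RNA-binding autoantigen, was covered over 53.4% in TKO, 3.6% in WT, 41.2% in D1240A and 32.3% in F1295A.

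H3K27me3 over GDF6, a bone morphogenetic factor gene on chromosome 8 (96142333 to 96160806), was 21.7% in TKO, 57.3% in WT, 26.1% in D1240A and 20.4% in F1295A. PMEL, a melanosome gene, was covered over 69.5% in TKO, 50% in WT, 8.8% in D1240A and 18.9% in F1295A. SLC26A9, an anion transporter gene, was covered over 25.2% in TKO, 38.7% in WT, 0.0% in D1240A and 22.5% in F1295A. GTSF1, a germline gene, was covered over 47.0% in TKO and 20.3% in WT.

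Windows of 10 kb at least 50% covered by H3K36me2 in all 4 lists numbered 5320, of which 477 lay outside the shared blocks. Outside these blocks 862 windows were covered in TKO alone, 178 in WT alone, 51 in D1240A alone and 486 in F1295A alone, while 478 were covered in TKO, D1240A and F1295A and not in WT. For H3K27me3, 557 windows outside the blocks were covered in all 4 lists and 132 in WT alone. For H3K27ac, 2675 were covered in all 4 lists and 341 in all but WT.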
